A study of Mus musculus with 12 samples.

How the data were processed

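Messenger RNA of 12 hearts was sequenced, 6 from the Control group and 6 from mice given carbon tetrachloride (CCl4). Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a stranded kit. Per the submitters' processing notes, Trimmomatic 0.36 and featureCounts of Subread 1.5.1 were used with GRCm38. The aligner, the annotation release and the strand setting of the counting were not given in the sources used here. The deposited values are RPKM (reads scaled by gene length and by the reads of the library) for 31722 gene symbols in 12 columns, 1 column per heart.

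RPKM is not a count. Each value was multiplied by the exon length of the gene in GENCODE release M21, which matched 30270 symbols (95.4%), to find the step that 1 read adds. In the 12 libraries 92.6% to 93.8% of low values (up to 30 steps) lay within 0.05 step of a whole number, where 10% would by chance. The totals in such steps ran from 26352337 (Control replicate 6) to 63408183 (CCl4 replicate 4). Control libraries held 41659755 ± 11439350 steps and CCl4 libraries 50624836 ± 7619350 steps (SD, n = 6 each). Between 71.1% and 75.3% of low values were even numbers of steps, so a step can be less than a whole fragment and the totals are relative depths. Among the symbols, 11 had been turned into calendar dates; 6 of them met the expression filter and none is named here.

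Groups and replicate numbers came from the sample titles. The tests, the 50 gene lists and the rule for named genes were set before the data were examined. Genes with an RPKM of at least 0.5 in at least 6 libraries were tested (14087 genes) with limma 3.58.1 in R 4.3.3, as a trend fit (lmFit, eBayes) to log2(RPKM + 1) over all 12 libraries with no covariate. The Benjamini-Hochberg adjusted p had to be under 0.05. A log2 fold change is CCl4 minus Control on the log2(RPKM + 1) scale, which understates the change of genes at low levels. The 37 lists with at least 5 tested members were tested with limma's camera, two-sided, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and an exact two-sided permutation test of each list's mean per library, over 924 splits, were alternatives. The log2 ratio of Myh7 to Myh6 was compared with the same exact test, whose smallest possible p is 0.00216. P-values of single genes and of the exact tests refer to the spread between these 12 mice. Camera compares the members of a list with all other genes tested. With the preset correlation its p rests mostly on the spread between genes, and its direction is relative to those other genes.

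The rule for named genes took the 5 genes with the smallest p in each direction when none passed. It left out gene models without a descriptive symbol and genes with a mean under 1 RPKM in both groups. It also took up to 4 members with the smallest p from each list, and 8 genes of general interest (Nppa, Nppb, Myh6, Myh7, Col1a1, Col3a1, Adrb1 and Atp2a2). Of the list members, the text names those that passed when adjusted over the list alone, up to 4, with at least 2 for a shifted list and 1 for another tested list. This smaller number was settled after the values were seen. Coordinates are 1-based on GRCm38, from the GENCODE release M21 annotation.

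The same steps were tested on simulated values of 13382 genes for CCl4 against Control. Each gene was drawn independently of the others, and only genes with more steps were changed. The steps called 43.8% of genes changed 1.5-fold, 75.8% of genes changed 2-fold and 96.8% of genes changed 4-fold, and 7 of 13189 genes with no change. Alternatives covered the pseudocount, the filter, the scaling of the libraries, array weights, a robust fit, the replicate number as a block, an exact rank-sum test and each library left out in turn. Further alternatives were chosen after seeing the data. These were voom on the recovered steps, covariates for atrial markers and Xist, a scaling without mitochondrial RNA, and pairs of libraries left out. The scaling without mitochondrial RNA also left out 6 nuclear gene models on chromosome 1 (24611535 to 24616197) that are copies of mitochondrial genes. In the table they carry reads that belong to mt-Co2, mt-Atp8 and their neighbours. They were added to that scaling after a first result with the 37 mitochondrial genes alone had been seen. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.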

Results

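Hearts of C57BL/6J mice were profiled by RNA sequencing in a Control group of 6 mice and a group of 6 mice given CCl4, a solvent toxic to the liver that is used to produce cirrhosis. The comparison asks what liver cirrhosis does to the heart. The relative depth of the 12 libraries ran from 26352337 to 63408183 steps of the RPKM scale. Pairs of libraries correlated across genes at r between 0.944 and 0.99, and no columns were identical. The labels give no sex, dose or collection time. Xist was at 19.4 to 31.1 RPKM in 4 hearts of each group and at 0.126 RPKM or less in replicates 2 and 5 of each group, where the Y-linked gene Ddx3y was at 6.18 to 7.79 RPKM.

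In hearts of CCl4-treated mice the genes of fatty acid use, the marker genes of endothelial cells and the immediate early genes lay lower than in Control hearts. Genes of the extracellular matrix, the mitochondrial genome and the red cell lineage lay higher. Of the circadian clock 12 of 16 tested genes lay higher and 4 lower, and the activators Arntl and Npas2, too low to be tested, were also lower. In the matrix list only CCl4 replicates 3, 5 and 6 lay above all Control hearts, and in the list of the mitochondrial genome only CCl4 replicates 1 and 2. Pdk4, the kinase that holds back pyruvate dehydrogenase, was at 58.5 ± 18.1 RPKM in Control and 20.6 ± 10.6 RPKM in CCl4 hearts (SD, n = 6 each). The endothelial nitric oxide synthase Nos3, whose own list was not shifted, was at 7.82 ± 0.971 and 5.07 ± 0.613 RPKM. No single gene passed the limma test, so the differences in these groups of genes are shifts of lists. None of the shifts held with an estimated correlation between genes (smallest adjusted p = 0.347).

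Of 14087 genes tested, 0 were higher and 0 were lower in CCl4 hearts at an adjusted p under 0.05, and the smallest adjusted p was 0.0731. At an unadjusted p under 0.05 there were 1435 genes, 226 higher and 1209 lower, where 704 are expected by chance on average. With the libraries scaled by the median of ratios this split was 772 higher and 788 lower, with quantile normalization 766 and 822, and with TPM scaling 144 and 1578. With mitochondrial RNA left out of the scaling it was 680 higher and 542 lower, so which side holds more genes depends on the scaling. The median of all genes was -0.0483 as deposited, -0.102 with TPM scaling and 0.0189 with mitochondrial RNA left out. Of 100 splits of the hearts into 6 and 6, the real one included, 12 gave at least 1435 genes at that unadjusted p. The count therefore does not exclude chance. Voom on the recovered steps gave 0 genes, with 1390 at an unadjusted p under 0.05. An exact rank-sum test also gave 0, with 1270, but this 0 decides little. With 6 hearts against 6, genes could pass it over 14087 genes only if very many were fully separated at once. The 107 genes with no overlap of the groups were too few for that. With limma's array weights 770 genes were higher and 1479 lower. Without Control replicate 1 the counts were 6 higher and 25 lower, without CCl4 replicate 1 they were 7 and 40, without CCl4 replicate 4 they were 1 and 0, and without CCl4 replicate 6 they were 0 and 2. With both libraries numbered 1 left out, a pair chosen after its values were seen, they were 102 and 221.

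Among genes that the naming rule admits, the 5 of smallest p on the higher side were Mir147, Sphk2, Bdh1, Dbp and Ccdc63, and none passed the test. Mir147 was at 0.344 ± 0.406 RPKM in Control and 3.15 ± 1.34 RPKM in CCl4 hearts (log2 fold change 1.62, SE 0.23, adjusted p = 0.0731, above the Control median in 6 of 6 hearts). It lies on chromosome 2 (122640803 to 122640881) inside AA467197, whose reads can be counted with it. Mir147 is short, so its values rest on few reads, and Control replicates 3, 5 and 6 were at 0 RPKM. AA467197 was itself higher in CCl4 hearts (0.103 ± 0.0579 and 0.516 ± 0.254 RPKM, exact permutation p = 0.00216). Bdh1, the enzyme that interconverts the ketone bodies acetoacetate and 3-hydroxybutyrate, was at 3.37 ± 1.41 and 8.57 ± 2.5 RPKM (1.14, SE 0.23, adjusted p = 0.0949, 6 of 6). Sphk2, a sphingosine kinase, was at 8.80 ± 1.67 and 14.3 ± 1.5 RPKM (0.65, SE 0.12, adjusted p = 0.0843). Dbp, a clock output factor, was at 18.5 ± 3.72 and 28.8 ± 2.84 RPKM (0.63, SE 0.13, adjusted p = 0.114). Sphk2 (chromosome 7, 45709467 to 45718002) overlaps Dbp (45705088 to 45710203) on the opposite strand, and with the strand setting not given their shared reads are uncertain. Ccdc63 was at 0.517 ± 0.164 and 1.31 ± 0.536 RPKM and overlaps the abundant Myl2.

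On the lower side the 5 genes were Pex11a, Mir324, Gsta1, Efnb1 and Snora31, each with an adjusted p of 0.0731 and below the Control median in 6 of 6 CCl4 hearts. Pex11a, a factor of peroxisome division, was at 1.82 ± 0.176 RPKM in Control and 1.10 ± 0.140 RPKM in CCl4 hearts (-0.43, SE 0.07). The glutathione transferase Gsta1 was at 1.59 ± 0.175 and 0.649 ± 0.286 RPKM (-0.67, SE 0.11), and near-identical copies can share its reads. Efnb1, an ephrin ligand, was at 3.20 ± 0.269 and 2.11 ± 0.203 RPKM (-0.43, SE 0.07). Mir324 was at 4.90 ± 0.456 and 1.73 ± 0.959 RPKM, and Snora31 at 4.63 ± 0.526 and 2.39 ± 0.721 RPKM. Both are short genes inside others, Mir324 in Dvl2 and, on the other strand, Acadvl, and Snora31 in Tpt1. The strand setting of the counts is not given, so reads of these genes can be counted with them; Acadvl was at 144.9 ± 25.63 and 107.7 ± 26.37 RPKM (exact permutation p = 0.0368).

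Of the 37 lists tested with camera, 19 were shifted, 9 up and 10 down. None of these calls held with an estimated correlation, where the smallest adjusted p was 0.347, or in the exact permutation test of list means, where the smallest adjusted p was 0.12. The preset correlation gives many calls in these hearts under other groupings as well: the other splits drawn, into 6 and 6, had a median of 13 lists shifted. In no list did a member pass over all genes tested.

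**Figure D1:**
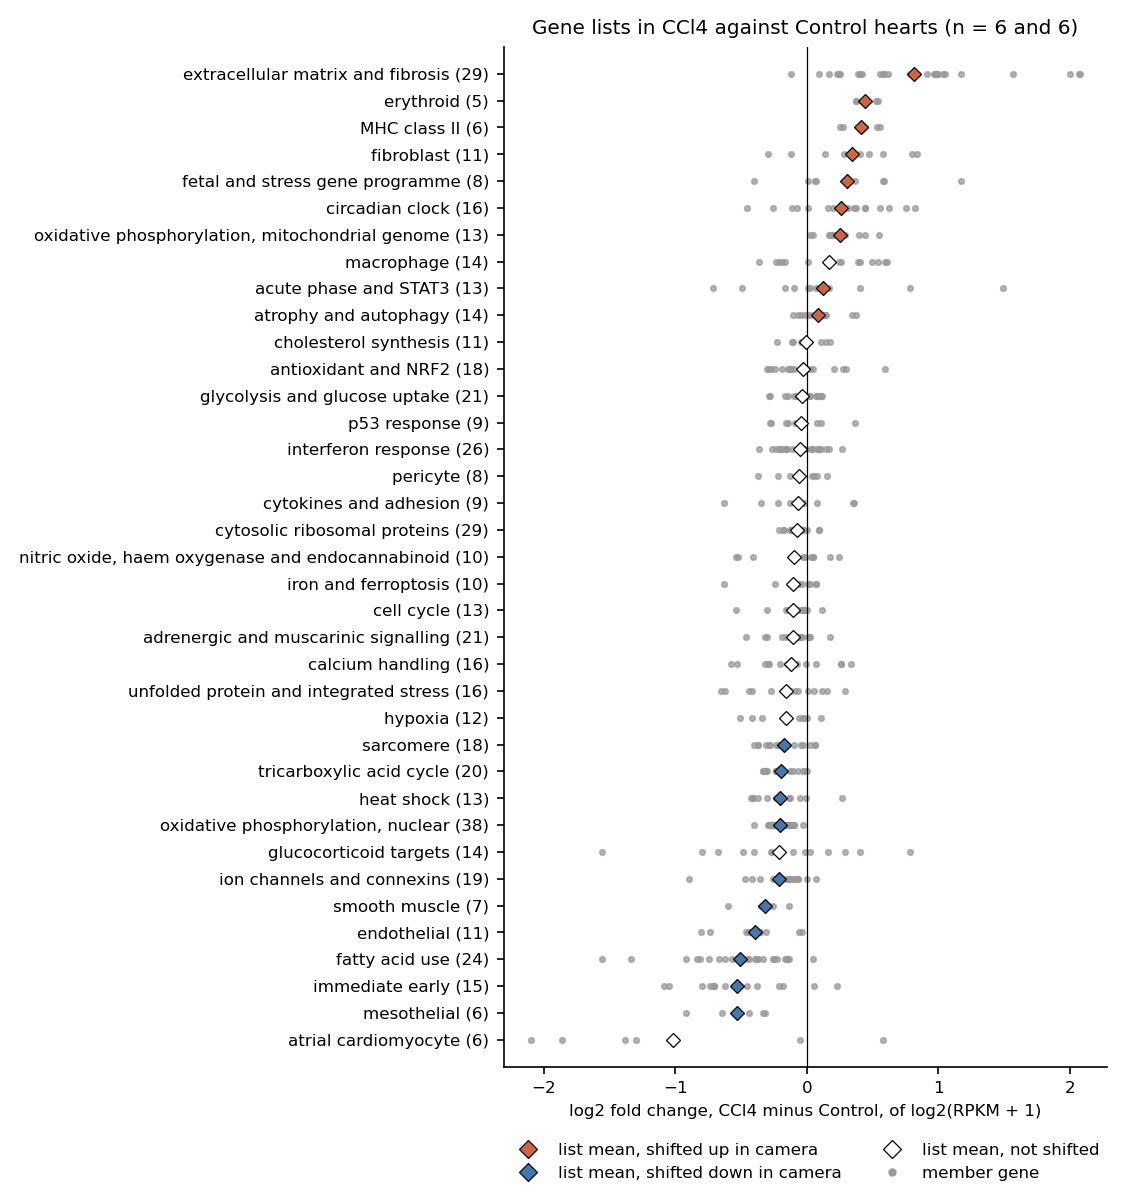
Log2 fold change (CCl4 minus Control, of log2(RPKM + 1)) of each tested member (grey points) and the mean (diamonds) of the 37 tested gene lists, with the number of tested members in brackets, n = 6 hearts per group. The extracellular matrix list has the highest mean among the lists shifted up (0.815) and the mesothelial list the lowest among those shifted down (-0.528), and under TPM scaling 2 of 13 mitochondrially encoded genes, 4 of 8 stress genes and 7 of 14 atrophy genes lie on the lower side.

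Of 24 genes of fatty acid use 23 were lower, with a mean log2 fold change of -0.51, and 10 were lower adjusted over the list alone. The list was shifted down (camera adjusted p = 4.67e-11; adjusted p = 0.347 with an estimated correlation), and its mean per heart lay below the Control median in all 6 CCl4 hearts. Pdk4 (log2 fold change -1.56, SE 0.30), the fatty acid carrier Cd36 (-0.81, SE 0.16) and the acyl-CoA thioesterases Acot1 (-0.84, SE 0.16) and Acot2 (-0.92, SE 0.22) had the smallest p. Cd36 was at 79.6 ± 16.4 RPKM in Control and 44.9 ± 8.76 RPKM in CCl4 hearts, with adjusted p = 0.0949. Acot1 and Acot2 are near-identical, so reads can be shared between them. Pdk4 lies on chromosome 6 (5483351 to 5496309) and Cd36 on chromosome 5 (17781690 to 17888801).

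All 38 nuclear genes of oxidative phosphorylation were lower, with a mean of -0.204 (camera adjusted p = 3.85e-06; adjusted p = 0.665 with an estimated correlation), though 1 was higher under median-of-ratios scaling. The mean was -0.105 with mitochondrial RNA left out of the scaling, where 2 of the 38 were higher, and -0.124 with quantile normalization. Ndufa1 was at 180 ± 14.6 and 152 ± 20.6 RPKM and Cox6c at 307 ± 33.6 and 254 ± 36.3 RPKM. The 13 protein genes of the mitochondrial genome were higher, with a mean of 0.25 and 5 higher adjusted over the list alone (camera adjusted p = 2.01e-11; adjusted p = 0.347 with an estimated correlation); under TPM scaling 2 of them were lower. In the mean of this list per heart only CCl4 replicates 1 and 2 (10.98 and 10.966) lay above all Control hearts (10.286 to 10.731). The other CCl4 hearts lay at 10.466 to 10.725. The unadjusted exact permutation p of the list was 0.0368, and 0.119 with both libraries numbered 1 left out. The cytochrome gene mt-Cytb was at 32180 ± 3719 and 38590 ± 4203 RPKM. mt-Nd4l, which overlaps mt-Nd4, had a log2 fold change of 0.44. mt-Co2 (0.40) and mt-Atp8 (0.55) are listed at only 1.96 and 5.22 RPKM in Control hearts, since nuclear copies on chromosome 1 carry their reads. Mitochondrial genes and these copies held 34.09 ± 3.05% of reads in Control and 38.43 ± 4.71% in CCl4 libraries. Of 20 genes of the tricarboxylic acid cycle 19 were lower, with a mean of -0.195 (camera adjusted p = 0.00758; adjusted p = 0.751 with an estimated correlation). Its member Sdhc was at 67.0 ± 8.39 and 54.2 ± 6.48 RPKM and Suclg1 at 38.4 ± 4.90 and 30.9 ± 5.32 RPKM. CCl4 replicate 3 had the lowest value of the nuclear list (6.81, other CCl4 hearts 7.36 to 7.47, Control hearts 7.231 to 7.703). Without it neither the nuclear list (mean -0.105, camera adjusted p = 0.431) nor the tricarboxylic acid list (-0.0873, 0.973) was shifted, and the latter list also lost its call without Control replicate 3 (0.0789), with median-of-ratios scaling (0.0734) and with quantile normalization (0.0707). Its mean was -0.0967 with mitochondrial RNA left out of the scaling. It was -0.317 without Control replicate 1 and CCl4 replicate 4, the libraries richest in atrial markers, here called atrium-rich. Control replicates 2, 3 and 5 also held much of the atrial gene Myl7 (140.7, 180.6 and 178.7 RPKM), so leaving out that pair does not level the groups.

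Endothelial markers were lower in all 11 genes, with a mean of -0.397, and 9 were lower adjusted over the list alone. This list was shifted down (camera adjusted p = 7.26e-09; adjusted p = 0.347 with an estimated correlation), and its mean per heart lay below the Control median in all 6 CCl4 hearts. Under median-of-ratios scaling 1 of the 11 was higher. Esam, a junction protein, was at 18.2 ± 1.43 and 13.3 ± 1.76 RPKM, the vascular cadherin Cdh5 at 43.5 ± 4.05 and 31.7 ± 5.43 RPKM, the receptor Tie1 at 12.2 ± 1.14 and 9.24 ± 0.930 RPKM and the fatty acid binding protein Fabp4 at 199 ± 24.7 and 145 ± 13 RPKM. The list of nitric oxide, haem oxygenase and endocannabinoid genes was not shifted (mean -0.0973, median 0.00781, camera adjusted p = 0.63). In it 3 genes were lower adjusted over the list alone: Nos3 (-0.54, SE 0.09), the inducible synthase Nos2 (-0.41, SE 0.11) and the monoacylglycerol lipase Mgll (-0.52, SE 0.14). Nos3 (chromosome 5, 24364810 to 24384474) is overlapped by the antisense gene Gm15587. The hypoxia list was not shifted (mean -0.16, camera adjusted p = 0.123), and the vascular growth factor Vegfa (176 ± 24.4 and 124 ± 22.5 RPKM) was lower adjusted over the list alone. Of the cytokine and adhesion list, Cxcl12 (14.0 ± 3.62 and 8.57 ± 2.04 RPKM) was.

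All 7 smooth muscle markers were lower, with a mean of -0.318 (camera adjusted p = 0.0063; adjusted p = 0.528 with an estimated correlation). The 3 lower adjusted over the list alone were the smooth muscle actin Acta2 (-0.60, SE 0.17), the myosin kinase Mylk (-0.31, SE 0.09) and Smtn (-0.29, SE 0.09). Pericyte markers were not shifted (mean -0.0592, camera direction up, adjusted p = 0.739), with Vtn at 5.77 ± 1.67 and 4.23 ± 1.37 RPKM. The 6 mesothelial markers were lower, with a mean of -0.528 (camera adjusted p = 0.013; adjusted p = 0.622 with an estimated correlation), among them Wt1 (0.831 ± 0.126 and 0.458 ± 0.125 RPKM), lower adjusted over the list alone, and Upk3b. Without Control replicate 1 neither the smooth muscle list (-0.237, camera adjusted p = 0.0687) nor the mesothelial list (-0.423, 0.092) was shifted, and the mesothelial list also lost its call without CCl4 replicate 5 (0.0637) and without CCl4 replicate 6 (0.0527). With an atrial marker score as a covariate the means were -0.139 and -0.217, and with both libraries numbered 1 left out -0.174 and -0.326, and neither list was shifted. The mesothelial mean was -1.29 with a pseudocount of 0.1 and -0.828 with array weights.

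Immediate early genes, which respond within minutes to growth signals and stress, were lower in 13 of 15, with a mean of -0.527, and 10 were lower adjusted over the list alone (camera adjusted p = 8.4e-08; adjusted p = 0.367 with an estimated correlation). Fos was at 3.53 ± 1.61 and 1.11 ± 0.336 RPKM (-1.05, SE 0.20, adjusted p = 0.0916), Klf4 at 17.8 ± 1.88 and 10.7 ± 3.07 RPKM, Btg2 at 6.94 ± 2.17 and 3.78 ± 0.859 RPKM and the phosphatase Dusp1 at 12.4 ± 3.75 and 6.62 ± 1.82 RPKM. Heat shock genes were lower in 12 of 13, with a mean of -0.202 (camera adjusted p = 0.013; adjusted p = 0.528 with an estimated correlation), and the call ended without CCl4 replicate 3 (mean -0.217, camera adjusted p = 0.0994) and with the filter set at a mean RPKM of at least 2 (-0.199, 0.0824), at means close to that of all hearts. With mitochondrial RNA left out of the scaling the mean was -0.117. Median-of-ratios scaling put 3 of the 13 heat shock genes on the higher side. The mitochondrial chaperonins Hspe1 (-0.41, SE 0.14) and Hspd1 (-0.42, SE 0.15), whose genes overlap, had the smallest p. Glucocorticoid targets were not shifted as a list (mean -0.208, camera adjusted p = 0.339), and 4 of 14 were lower adjusted over the list alone: Pdk4, Sgk1 (-0.68), Dusp1 (-0.80) and Errfi1 (-0.40). The unfolded protein and integrated stress list was not shifted (mean -0.158, camera adjusted p = 0.358), with Atf3 at 2.79 ± 0.987 and 1.42 ± 0.485 RPKM.

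Circadian clock genes were higher in 12 of 16 and lower in 4, with a mean of 0.26 (camera adjusted p = 7.36e-07; adjusted p = 0.347 with an estimated correlation). Adjusted over the list alone 6 were higher and 1 lower. Dbp, the period gene Per3 (0.75, SE 0.23) and the repressor Ciart (0.44, SE 0.15) were among those higher, and Clock, the activator of the loop, was the one lower (1.5 ± 0.185 and 1.10 ± 0.235 RPKM). The activators Arntl (0.686 and 0.222 RPKM) and Npas2 (0.550 and 0.299 RPKM), also members of the list and lower in CCl4 hearts, did not meet the expression filter. Under TPM scaling all 18 listed genes were tested, 11 higher and 7 lower, with a mean of 0.144. With both libraries numbered 1 left out the mean was 0.403. In the clock list 5 of 6 CCl4 hearts lay above the Control median and CCl4 replicate 1 at it (2.134, between Control hearts at 2.127 and 2.14), and Control replicate 1 lay among the CCl4 hearts (2.59, other Control hearts 1.97 to 2.19).

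**Figure D2:**
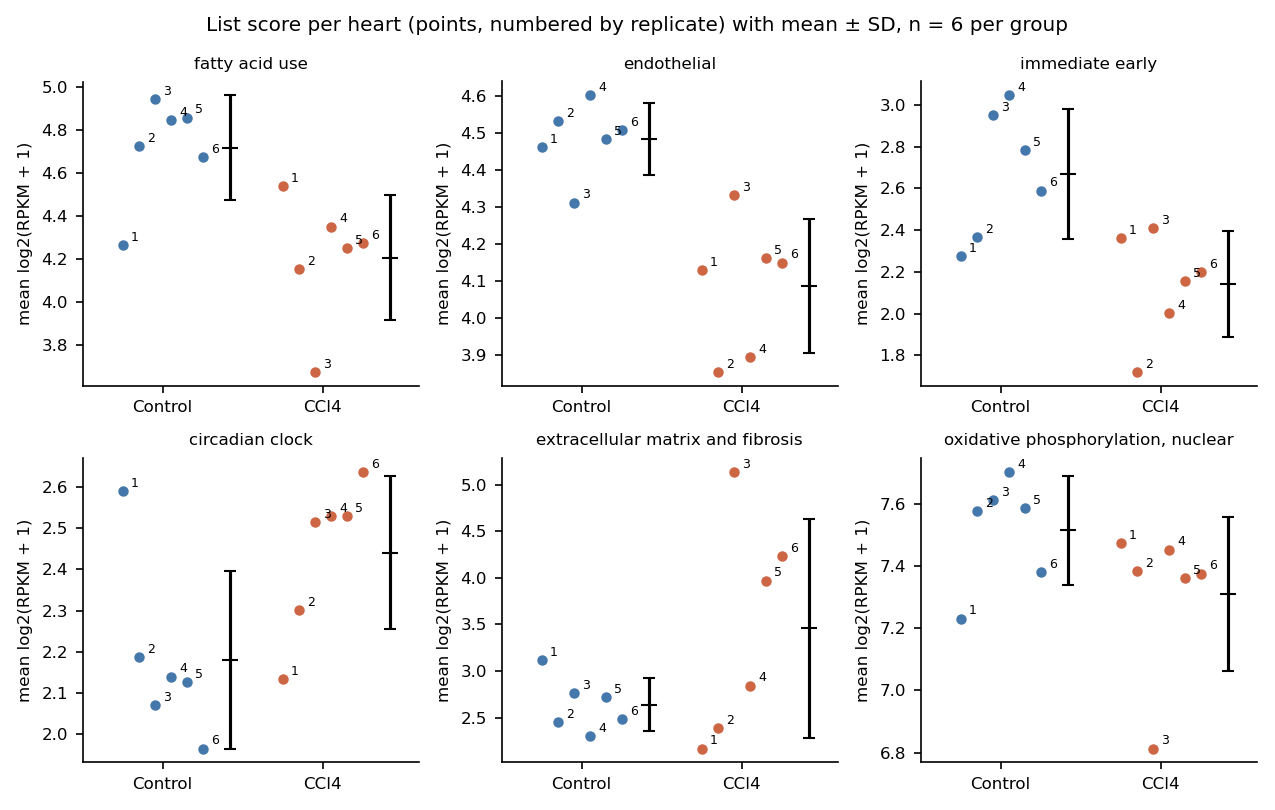
Mean log2(RPKM + 1) over the tested members of 6 gene lists in each heart (points, numbered by replicate), with the group mean and SD (n = 6). In the fatty acid and endothelial lists all CCl4 hearts lie below the Control median, and in the nuclear oxidative phosphorylation list CCl4 replicate 3 lies at 6.81.

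Of 29 genes of the extracellular matrix and fibrosis list 28 were higher, with a mean of 0.815 (camera adjusted p = 1.18e-15; adjusted p = 0.416 with an estimated correlation; exact permutation p = 0.145), and 0 passed adjusted over the list alone. The hearts were uneven. Mean scores were 5.137, 3.97 and 4.232 in CCl4 replicates 3, 5 and 6, and 2.169, 2.39 and 2.844 in CCl4 replicates 1, 2 and 4, against 2.305 to 3.116 in Control hearts. The collagens Col1a1 (12.2 ± 4.51 and 34.8 ± 32.3 RPKM) and Col3a1 (27.8 ± 9.45 and 81.7 ± 73.3 RPKM) were above the Control median in 4 of 6 CCl4 hearts. Cilp (2.07, SE 0.71) and Col8a1 (1.57, SE 0.52) were above it in 5 of 6. Without CCl4 replicate 3 the mean of the list was 0.479. Fibroblast markers were higher in 9 of 11, with a mean of 0.347 (camera adjusted p = 0.000198; adjusted p = 0.528 with an estimated correlation), or 0.176 without CCl4 replicate 3, 0.523 with array weights and 0.576 with both libraries numbered 1 left out, with Lum at 10.3 ± 5.60 and 20.2 ± 11.8 RPKM and Pi16 at 10.8 ± 5.41 and 21.3 ± 13.3 RPKM. The matrix score less the fibroblast score was 0.469 higher in CCl4 hearts, a difference that the exact permutation test did not set apart from the spread (p = 0.158).

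Stress genes of the heart were higher in 7 of 8, with a mean of 0.306 (camera adjusted p = 0.00876; adjusted p = 0.563 with an estimated correlation), and in 4 of 8 under TPM scaling. Ankrd1, a stretch-responsive cofactor, was at 591 ± 254 and 1427 ± 705 RPKM and Xirp2, which overlaps Gm13601, at 20.1 ± 2.72 and 32.5 ± 12.6 RPKM. The natriuretic peptides spread widely: Nppa was at 4251 ± 5098 and 5356 ± 4383 RPKM and Nppb at 169 ± 45.6 and 203 ± 137 RPKM. Nppa is also an atrial marker and was highest in the atrium-rich Control replicate 1 (14180 RPKM) and CCl4 replicate 4 (11080 RPKM). In Control replicates 4 and 6, low in the atrial gene Myl7, it was at 681.6 and 576.5 RPKM. In CCl4 replicates 1, 2, 3, 5 and 6, also low in Myl7, it was at 801.7, 1340, 9552, 2689 and 6675 RPKM. These hearts were set apart after the values were seen, and no test was made on them alone. The log2 ratio of Myh7 to Myh6, the slow over the fast myosin heavy chain, was -5.83 ± 0.173 in Control and -5.49 ± 0.62 in CCl4 hearts (SD, n = 6 each; difference 0.344, exact permutation p = 0.201). Myh7 overlaps Mhrt, Gm29015 and Gm17428 on the other strand and Nppa overlaps Gm13054, and with the strand setting not given their values and the ratio can hold reads of these genes. CCl4 replicate 3 had the highest ratio (-4.28), and without it the difference was 0.102. Without CCl4 replicate 3 the mean of the stress list was 0.132, without CCl4 replicate 1 it was 0.461, and with both libraries numbered 1 left out it was 0.53. With no filter on low values this list was not shifted (mean 0.261, camera adjusted p = 0.129).

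Sarcomere genes were lower in 15 of 18, with a mean of -0.176 (camera adjusted p = 0.0113; adjusted p = 0.665 with an estimated correlation). The troponin Tnnc1 was at 3122 ± 494 and 2365 ± 432 RPKM, Csrp3 at 184 ± 23.9 and 148 ± 16.1 RPKM and Myh6 at 16210 ± 1462 and 13470 ± 2388 RPKM; Myh7 was at 283 ± 25.9 and 303 ± 84.6 RPKM. Ion channel and connexin genes were lower in 17 of 19, with a mean of -0.21 (camera adjusted p = 0.0113; adjusted p = 0.665 with an estimated correlation), led by the potassium channels Kcnk3 (-0.42, SE 0.12) and Kcna5 (-0.47, SE 0.16). Neither list was shifted without CCl4 replicate 3 (means -0.113 and -0.153, camera adjusted p = 0.842 and 0.705). The sarcomere list also lost its call with median-of-ratios scaling (mean -0.11, camera adjusted p = 0.151), with quantile normalization (-0.0996, 0.0836) and without mitochondrial RNA in the scaling (-0.0769, 0.0785). The channel list lost its call with the atrial score as a covariate (mean -0.128, camera adjusted p = 0.188). Calcium handling genes were not shifted (mean -0.119, camera adjusted p = 0.63). Of these the calcium pump Atp2a2 was at 194 ± 43.3 and 138 ± 61.9 RPKM and the channel Cacna1c at 4.84 ± 0.571 and 6.02 ± 0.964 RPKM. Adrenergic and muscarinic genes were not shifted (mean -0.107, camera adjusted p = 0.242), with the receptor Adrb1 at 0.753 ± 0.115 and 0.539 ± 0.151 RPKM and Adra1b at 1.11 ± 0.303 and 0.701 ± 0.145 RPKM.

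**Figure D3:**
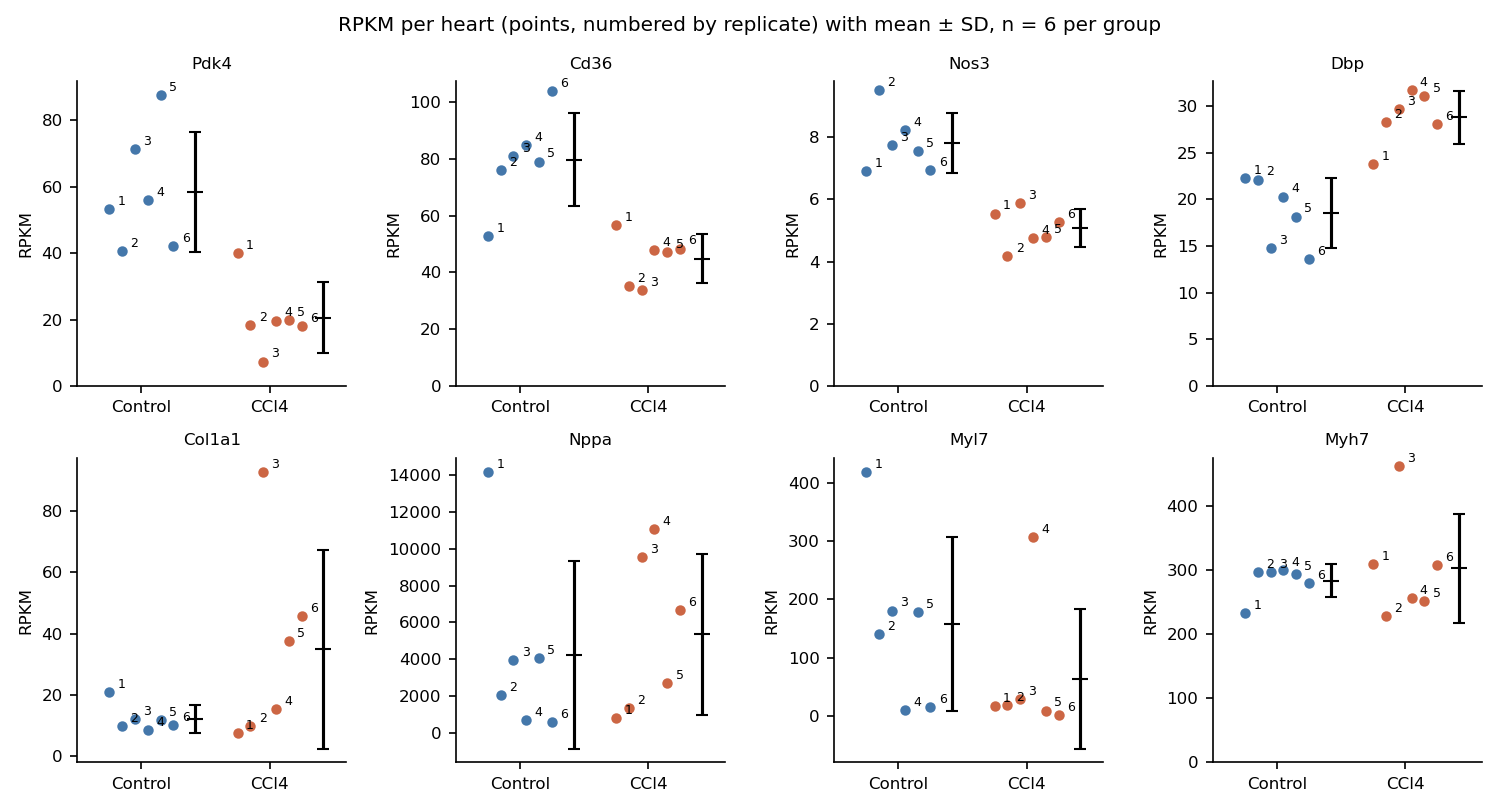
RPKM of 8 genes in each heart (points, numbered by replicate) with mean and SD (n = 6 per group). Pdk4, Cd36, Nos3 and Dbp differ in group mean with smaller spread than Col1a1, Nppa and Myl7, and Myh7 is highest in CCl4 replicate 3.

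Red cell genes were higher in all 5 tested, with a mean of 0.446, and all 5 were higher adjusted over the list alone (camera adjusted p = 7.36e-07; adjusted p = 0.347 with an estimated correlation). Alas2, the haem synthesis enzyme of red cells, was at 2.30 ± 0.684 and 3.84 ± 1.16 RPKM, Hba-a2 at 12.3 ± 3.26 and 16.6 ± 3.05 RPKM, Hbb-bt at 11.2 ± 4.11 and 16.3 ± 3.70 RPKM and Hba-a1 at 42.3 ± 12.3 and 53.8 ± 7.98 RPKM. The globin copies are near-identical and can share reads. The 6 MHC class II genes were higher, with a mean of 0.412 (camera adjusted p = 2.52e-05; adjusted p = 0.416 with an estimated correlation), or 0.235 without CCl4 replicate 3. H2-Eb1 was at 18.8 ± 2.89 and 30.6 ± 16.4 RPKM and H2-DMa at 0.546 ± 0.0876 and 0.873 ± 0.369 RPKM. Macrophage markers were not shifted (mean 0.171, camera adjusted p = 0.0649), and Lyve1 was at 7.20 ± 1.20 and 5.45 ± 1.48 RPKM.

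Acute phase and STAT3 genes were higher in 9 of 13, with a mean of 0.127 (camera adjusted p = 0.0449; adjusted p = 0.665 with an estimated correlation), with Serpina3n at 0.911 ± 0.876 and 7.63 ± 10.2 RPKM and the metallothionein Mt2 at 4.33 ± 3.45 and 7.31 ± 2.33 RPKM. This call ended with a pseudocount of 0.1 (camera adjusted p = 0.0598) or 0.5 (0.051), no filter (0.113), median-of-ratios scaling (0.229), quantile normalization (0.222), array weights (0.155), the replicate number as a block (0.0645) and mitochondrial RNA left out of the scaling (0.253). It also ended without any of Control replicates 2, 3, 4 and 6 or CCl4 replicates 2, 3 and 4. Without CCl4 replicate 3 the mean was 0.0159, without CCl4 replicate 4 0.0683 and without CCl4 replicate 2 0.221. Without Control replicate 4 it was 0.0639 and without Control replicate 6 0.0722. The mean was 0.0791 with no filter. It was 0.164 to 0.192 with median-of-ratios scaling, quantile normalization, array weights or mitochondrial RNA left out of the scaling. Without Control replicate 1 the mean was 0.237, without CCl4 replicate 1 0.226, without both 0.336, with the atrial covariate 0.297, with the filter at a mean RPKM of at least 2 0.279 and with TPM scaling 0.0798. Atrophy and autophagy genes were higher in 10 of 14, with a mean of 0.0874 (camera adjusted p = 0.0101; adjusted p = 0.665 with an estimated correlation), and in 7 of 14 under TPM scaling. The autophagy receptor Sqstm1 was at 37.7 ± 5.25 and 48.9 ± 10.8 RPKM and the ubiquitin ligase Fbxo32 at 7.21 ± 2.30 and 9.61 ± 2.69 RPKM. Without CCl4 replicate 4 this list was not shifted (mean 0.0442, camera adjusted p = 0.077); its mean was 0.0578 without Control replicate 2, 0.156 without CCl4 replicate 1 and 0.0492 without CCl4 replicate 6. With no filter it was not shifted either (camera adjusted p = 0.0923). Its mean was 0.0242 with TPM scaling, and 0.142 to 0.196 with median-of-ratios scaling, quantile normalization, array weights, the atrial covariate, mitochondrial RNA left out of the scaling or both libraries numbered 1 left out.

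The other tested lists were not shifted. Camera adjusted p was 0.749 for interferon response (mean -0.0483; Rsad2 -0.36), 0.716 for glycolysis and glucose uptake (-0.0368; Pfkfb1 -0.29), 0.931 for p53 response (-0.0458; Fas -0.28) and 0.421 for cholesterol synthesis (-0.00877; Hmgcs1 -0.23). In these 4 lists and in cytokines and adhesion (mean -0.0697, adjusted p = 0.877) camera pointed up while the mean was below 0. It was 0.931 for antioxidant and NRF2 genes (-0.0276; Sod1 -0.29), 0.931 for iron and ferroptosis (-0.101; Lpcat3 -0.24), 0.877 for cell cycle (-0.105; Ccnd1 -0.54) and 0.242 for cytosolic ribosomal proteins (-0.0748; Rpl27 -0.21). The sign of several of these small means depends on the scaling. With mitochondrial RNA left out it was above 0 for interferon response (0.0316), glycolysis (0.0535, 17 of 21 higher), p53 response (0.0256), cholesterol synthesis (0.0445), antioxidant genes (0.0564), ribosomal proteins (0.0231, 20 of 29 higher) and pericyte markers (0.0277). It was also above 0 with quantile normalization for these lists except p53 response, and with median-of-ratios scaling for interferon response, glycolysis, antioxidant genes and cholesterol synthesis.

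Atrial markers differed between hearts more than between groups, and the rich hearts were not evenly shared by the groups. Myl7, the atrial myosin light chain, was at 157 ± 150 RPKM in Control and 63.1 ± 120 RPKM in CCl4 hearts. It was at 419, 140.7, 180.6 and 178.7 RPKM in Control replicates 1, 2, 3 and 5 and at 307 RPKM in CCl4 replicate 4. The other Control hearts were at 9.467 and 14.6 RPKM and the other CCl4 hearts at 0.811 to 28.72 RPKM. The atrial list was not shifted (mean -1.02, camera adjusted p = 0.421). Of 13 lists with fewer than 5 tested members no test was made. The mean log2 fold change was 0.0817 for 4 renin-angiotensin-aldosterone genes, -0.0173 for 1 bile acid sensing gene, 0.077 for 1 monocyte and neutrophil gene, 0.0752 for 2 T and NK cell genes, 0.421 for 2 B cell genes, 0.535 for 2 brown adipocyte genes, -0.999 for 4 white adipocyte genes, -0.0829 for 3 Schwann cell genes, -0.346 for 3 hepatocyte genes, -0.196 for 3 skeletal muscle genes, -0.253 for 1 thymus gene and 0.102 for Xist. Of the lung list 0 genes met the filter.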

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

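The tests of swapped labels and of atrial tissue and the fits without both libraries numbered 1 were chosen after the data were seen; for atrial tissue the value expected was set before that test was run. In 28 of 254 groups of 6 values the highest or lowest heart stood apart from the others of its group, where 13 are expected by chance at 1 in 20. Control replicate 1 was that heart in 12 of them, CCl4 replicate 1 in 7, CCl4 replicate 3 in 5, and Control replicates 3 and 6 in 2 each. The value given with each is its gap to the nearest heart as a share of the range of its group.

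Control replicate 1 stood above the other Control hearts in the clock list (0.646), the glucocorticoid target list (0.722), Fas (0.683), Per3 (0.682) and Pi16 (0.656). It stood below them in Tnnc1 (0.678), Csrp3 (0.646), Sdhc (0.631), Hspe1 (0.843), Klf4 (0.708), Ccnd1 (0.71) and Myh7 (0.727). CCl4 replicate 1 stood above the other CCl4 hearts in Tnnc1 (0.76), Acot1 (0.72), Acot2 (0.637), Sod1 (0.762) and Vegfa (0.651), and below them in Sphk2 (0.65) and Per3 (0.64). CCl4 replicate 3 stood below the other CCl4 hearts in the sarcomere list (0.711), the nuclear oxidative phosphorylation list (0.831), Suclg1 (0.782) and Myh6 (0.689), and above them in the Myh7 to Myh6 ratio (0.714). Control replicate 3 was low in Gsta1 (0.643) and Fabp4 (0.695), and Control replicate 6 in the nitric oxide list (0.625) and Myh6 (0.64).

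In the genes that part the other 10 hearts, each heart numbered 1 resembled the opposite group. Over the 323 genes past the limma test in those 10 hearts, with the Control mean at 0 and the CCl4 mean at 1, Control replicate 1 had a median position of 0.856 and CCl4 replicate 1 of 0.222, while other hearts, each left out in turn, lay at -0.0965 to 0.159 (Control) and 0.625 to 0.916 (CCl4). With the trend on the atrial score removed Control replicate 1 stayed at 0.856, although single genes moved by a median of 0.131. That argues against atrial tissue alone for these genes only. They were picked for small spread within groups over hearts of differing atrial score, which tends to leave out genes that follow it. The atrial score of Control replicate 1 (6.2) also lay above those of the hearts that set the trend (highest 5.86, CCl4 replicate 4). Swapped labels may account for the pair and cannot be told apart from hearts that differ in themselves: Control replicate 1 lay within the CCl4 range, CCl4 replicate 1 just above the Control range, and Mir147, Pex11a and Gsta1 kept both hearts on their labelled side, though these genes were picked with those labels. Exchanging the 2 labels gave 599 genes past the test, against at most 133 for the other exchanges among 36, a pair picked because it stood out; all values in the report use the labels as given.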

How the results depend on the processing

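The atrial and Xist covariates, voom, the scaling without mitochondrial RNA and the pairs of libraries left out were chosen after seeing the data, and the count of splits for genes past the test was set after its result was seen. Counts of genes past the test (0 and 0) became 770 higher and 1479 lower with array weights, which gave CCl4 replicate 5 a weight of 5.7 and CCl4 replicate 3 of 0.258. They became 102 and 221 with both libraries numbered 1 left out and 1 lower with the atrial covariate. They became 1 higher with Control replicate 1 and CCl4 replicate 4 left out, the pair richest in atrial markers. The other settings with all 12 libraries gave 0 and 0. Among them the exact rank-sum test could pass genes only if very many were fully separated at once, so its 0 decides little. Leaving out single libraries gave 0 to 7 higher and 0 to 40 lower: 6 and 25 without Control replicate 1, 7 and 40 without CCl4 replicate 1, 1 higher without CCl4 replicate 4 and 2 lower without CCl4 replicate 6, and 17 genes passed both without Control replicate 1 and without CCl4 replicate 1. The number of lists shifted (19) was 0 with an estimated correlation and 0 in the exact test, 15 to 20 without single libraries (15 without CCl4 replicate 3) and 16 to 22 otherwise. The Myh7 to Myh6 difference was 0.102 (without CCl4 replicate 3) to 0.438. Signs turned for Nppb with TPM scaling (-0.00357), array weights (-0.0407), the atrial covariate (-0.139) and both libraries numbered 1 left out (-0.00788), with -0.202 to 0.262 without single libraries. They turned for Myh7 with TPM scaling (-0.0167), array weights (-0.125) and both libraries numbered 1 left out (-0.0101), with -0.0707 to 0.132 without single libraries. The tricarboxylic acid list had means of -0.263 to -0.0873 without single libraries, and camera pointed up without CCl4 replicate 3. Apart from the settings' own construction the cause was not tested. The replicate numbers were not taken to pair the hearts, since the labels name no shared animal or batch and not every pair correlated over 0.1. Deviations of same-numbered hearts correlated at -0.47, 0.23, -0.024, -0.25, 0.18 and 0.14, 4 of 12 hearts correlated best with their own number, and Xist and Ddx3y levels went with the number in both groups. With the replicate block the counts were 0 and 0 genes and 19 lists, where 18 kept their call and the acute phase list lost it (0.0645). Of 100 splits of the hearts into 6 and 6, among 462, 100 give at least as many genes past the test as the real 0 by construction, which says nothing about chance (highest other 7). At an unadjusted p under 0.05, 12 gave as many genes as the real 1435 (highest other 2906), so chance is not excluded, and a structure of the samples beyond the groups is present. As many lists as the real 19 came from 2 of the 100 splits, the real one included, and the other gave 23, with a median of 13 over the other splits drawn, so this share is under 5% while the real count is not the highest; no single list passed the exact test. For genes with array weights (2249) only the real one of the 100 splits drawn gave as many (highest other 841), which argues against chance for that fit alone. Over all 462 splits, 30 gave as many genes with no overlap of the groups as the real 107, so chance is not excluded there. At this depth and spread the simulated test called 43.8% of genes changed 1.5-fold. The simulation held no structure shared between genes, so this rate need not hold in these hearts.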

Other observations

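Tests of mitochondrial RNA in the scaling, of atrial tissue, of the number of endothelial cells or cardiomyocytes and of the clock phase, and the genes Arntl, Npas2, Per2, Cry1, Nr1d1, Cldn5, Kdr, Emcn and Ly6c1, were chosen after values were seen; for atrial tissue the value expected of the endothelial list was set before that list was fitted with the atrial covariate. The clock activator Arntl was at 0.686 ± 0.281 RPKM in Control and 0.222 ± 0.139 RPKM in CCl4 hearts (SD, n = 6 each, exact permutation p = 0.0108), and its partner Npas2 at 0.550 ± 0.105 and 0.299 ± 0.0649 RPKM (exact permutation p = 0.00216, the smallest possible). Dbp was higher in CCl4 hearts (exact permutation p = 0.00216), and Per2 was at 3.07 ± 2.79 and 5.55 ± 1.85 RPKM (exact permutation p = 0.0519). Not all targets of the activators lay on that side, as Nr1d1 was at 14.96 ± 4.002 and 10.56 ± 2.772 RPKM (log2 fold change -0.45, limma adjusted p = 0.452). Of the arms of the clock only a score of 9 target genes was tested as a set, and its result is given below with fatty acid use. The labels give no hour of collection.

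With both libraries numbered 1 left out, 5 hearts against 5, limma called 102 genes higher and 221 lower. Leaving out the pair that most opposed its groups inflates these counts, and leaving out other pairs gave at most 179 genes. Of the fatty acid list 10 of 24 genes were lower, among them Pdk4 (-1.79), Acot2 (-1.25), Acot1 (-1.06) and Cd36 (-0.99). Of the clock list 9 of 16 were higher, among them Per2 (1.26), Per3 (1.09) and Cry1 (0.74), and 1 was lower, the repressor Nr1d1 (-0.69). Of the immediate early list 7 of 15 were lower, among them Fos (-1.19), and Nos3 was lower (-0.59). With an estimated correlation 0 lists were shifted. The exact permutation test also gave 0, but lists could pass it only if several reached its smallest possible p together. With 5 hearts against 5 that smallest exact permutation p is 0.00794. The fatty acid, clock and red cell lists each had it, with an exact permutation adjusted p of 0.0979. No conclusion is drawn from the 0 of that test.

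Endothelial markers were lower in CCl4 hearts (mean -0.397). Mitochondrial RNA in the scaling as the whole cause is argued against, since the mean was -0.304 with it left out (camera adjusted p = 4.03e-09), and so is atrial tissue, with a mean of -0.445 under the atrial covariate (2.53e-09). The list's call was lost with an estimated correlation (adjusted p = 0.347) and in the exact permutation test (adjusted p = 0.12), without these corrections. The members spread from Cldn5 (-0.81) and Kdr (-0.73) to Emcn (-0.06) and Ly6c1 (-0.03), with a heterogeneity p of 0.0181 over the 11 genes (Q = 21.5). That test cannot decide whether endothelial cells were lost uniformly. It takes the genes as independent though they share the same hearts, and genes at low levels change less on the log2(RPKM + 1) scale. A loss of endothelial cells stays open, as does an effect of the treatment on gene activity, since no test here tells these apart.

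Genes of fatty acid use were lower in CCl4 hearts (mean -0.51). Mitochondrial RNA in the scaling as the whole cause is argued against, since the mean was -0.422 with it left out (camera adjusted p = 8.39e-12). Before that correction the camera adjusted p was 0.347 with an estimated correlation. Fewer cardiomyocytes as the whole cause are also argued against, since the fatty acid score less the sarcomere score was still lower by -0.334 (exact permutation p = 0.00433). The sarcomere score itself differed by -0.176, a share of 0.345 of the fatty acid difference, so a part stays open. Another clock phase at collection may contribute and cannot be told apart from the treatment: within groups the clock target and fatty acid scores of the 12 hearts correlated at r = -0.488 (permutation p = 0.122; rho = -0.329, permutation p = 0.324), the only such relation computed, and at -0.155 without Control replicate 1 and CCl4 replicate 6. The clock targets were 0.365 higher in CCl4 hearts (exact permutation p = 0.0325). An effect of the CCl4 treatment or of the liver disease on fuel use stays open, untested against feeding or the hour of collection.

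The extracellular matrix list kept a mean of 0.841 with the atrial score as a covariate (camera adjusted p = 7.65e-11). Without the covariate its adjusted p was 0.416 with an estimated correlation and its exact permutation p was 0.145, and the mean was 0.479 without CCl4 replicate 3.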
